A study of Homo sapiens with 6 samples.

How the data were processed

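RNA was measured in 6 libraries of a bone-homing variant of MDA-MB-231, a human triple-negative breast cancer cell line, after no flow, flow at 1 mL/min or flow at 15 mL/min. There were 2 libraries per condition. Per the labels' protocols, cells were lysed in TRIzol and poly(A) RNA was made into libraries with a KAPA stranded mRNA kit. The authors deposited a table of raw counts per gene, with 60591 rows named by gene symbol and 1 column per library. The submitters' processing notes name STAR, featureCounts and hg38, without versions or settings, and the gene annotation is not given in the sources used here. Each column was matched to its sample through the column name in the labels, and every row names a gene.

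How the reads were counted was checked on the table. Where an annotated gene lies within the exons of another gene on the opposite strand, its count density was a median of 0.0127 of the other gene's over 101 pairs, as strand-specific counting would give. Over 11 such pairs on the same strand the median was 1.25. The counts of SENP3-EIF4A1, a readthrough gene, were 0.936 to 0.952 of the sum of SENP3 and EIF4A1. Genes that overlap on the same strand therefore share reads in these counts, and their values are uncertain. Values of processed pseudogenes and of ribosomal protein and histone genes, which have near-identical copies, are uncertain for a similar reason. Gene positions, transcript lengths and GC contents came from GENCODE 29 on GRCh38, in which 56509 of the 60591 symbols matched 1 gene. Positions are counted from 1.

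Library totals were 17822642 and 23544307 counts for static, 45174328 and 47067620 for low flow, and 43965176 and 53279537 for high flow. The column names place the static and low flow libraries in 1 lane and both high flow libraries in another, with differently named alignment files. Lane and flow rate cannot be told apart in the comparisons with high flow, and no value within a lane can be given for them. Static and low flow share a lane. The 2 libraries of a condition are numbered as replicates by the labels, which do not say that they were separate cultures, so p-values measure only the spread between these libraries. Replicates were not copies of 1 library: the chi-square per degree of freedom between the 2 libraries of a condition was 14.9 for static, 32.0 for low flow and 12.9 for high flow.

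Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust dispersion estimates and all 6 libraries in 1 fit with 3 residual degrees of freedom. The default expression filter, with a minimum count of 10, left 20676 genes. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each of the 3 comparisons, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken from the test statistic. CPM values, counts scaled by library size, were computed here from the deposited counts with the TMM factors and are given as mean ± SD over 2 libraries. The 28 gene lists were tested with camera in limma 3.58.1, which asks whether a list's genes rank apart from the other tested genes, with a preset inter-gene correlation of 0.01. No list passed the threshold in any comparison when the correlation was estimated from the residuals, so that p is printed beside each call.

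The comparisons, lists, marker sets, rule for named genes and all but 1 of the alternatives below were set before the data were examined. The rule took, per comparison, the 10 largest and the 10 smallest log2 fold changes among genes with a gene-table symbol, a passing adjusted p, a mean of at least 4 CPM and groups that did not overlap. It also took up to 4 members of each list called, by p, in the direction of the call, and 16 genes in every comparison whatever their p: FOS, EGR1, CCN1, CCN2, ANKRD1, PTGS2, KLF2, PTHLH, IL11, MMP1, CXCR4, VEGFA, CXCL8, IL6, HMOX1 and PIEZO1. Other members of a list that are named were chosen after their values were seen.

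The fit was tested on simulated counts of 20676 genes with 200 changed genes and 1 list moved 1.3-fold, which was called in every comparison. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that was not measured. For low flow against static the fit recovered 68.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97.0% of those changed 3-fold. For high flow against static the shares were 56.7%, 95.5% and 100%, and for high flow against low flow they were 76.1%, 91.0% and 97.0%. The fit called 12, 20 and 17 unchanged genes in these comparisons, and 0, 1 and 1 of the 27 unmoved lists. Each gene was drawn independently, so the simulated lists had no inter-gene correlation. In low flow against static the correlation estimated from the data ran from -0.04 to 0.92 across lists. The simulation therefore does not measure how often correlated lists are falsely called. Alternatives were another normalization (RLE), no expression filter, DESeq2 1.42.0, only the 4 libraries compared, a replicate block, thinning to the smallest library, leaving out mitochondrially encoded genes and the 20 genes with most counts, and leaving out each library. An adjustment of each library for its trend with transcript length and GC content, by offsets from a smooth fit, was added after the data were seen. Of the tested genes, 96.8% had a length and GC value.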

Results

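The series compared bone-homing MDA-MB-231 breast cancer cells in a 3-dimensional model at rest and under fluid shear, as a model of the fluid movement that mechanical loading causes in bone. RNA from 2 libraries each was sequenced after no flow (static), flow at 1 mL/min (low flow) and flow at 15 mL/min (high flow). The comparisons ask what each flow rate changed against static and where the flow rates differed. Depth ran from 17822642 counts in the first static library to 53279537 in the second high flow library. On the first principal component of log CPM, which held 46.7% of the variance, the static libraries lay at -39.4 and -47.1, the low flow libraries at -0.12 and 29.0, and the high flow libraries at 30.9 and 26.6.

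Under low flow, some genes of matrix, adhesion and TGF-beta signalling were higher than in static cells. FBN2, which encodes a microfibril protein (chromosome 5, 128257909 to 128659185), rose from 2.00 ± 0.56 to 7.72 ± 2.06 CPM (SD, n = 2), a log2 fold change of 1.93 with an SE of 0.24 and an adjusted p of 0.000285. NEDD9, a scaffold of focal adhesion signalling (chromosome 6, 11183298 to 11382348), rose 3.09-fold (adjusted p = 0.0139). LOXL4, a collagen cross-linking enzyme, rose 2.56-fold, the integrin subunit ITGA10 2.18-fold and the kinase RIPK4 2.26-fold. AGR2, SNED1, the pseudogene FER1L4 and MIR29B2CHG, the host gene of miR-29 precursors, rose 2.22-fold to 2.72-fold. MIR4758, within LAMA5 on the same strand, rose 2.96-fold and shares reads with it.

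Of the 28 gene lists fixed in advance 7 were called higher and 7 lower, and 0 with an estimated correlation. In the list of shear stress and mechanosensing genes, 8 of 25 tested members rose, 8 adjusted over the list alone, and 0 fell (camera adjusted p = 0.000202, and adjusted p = 0.248 with an estimated correlation). They included PTGS2, the inducible cyclooxygenase (1.89-fold, adjusted p = 0.0001), endothelin gene EDN1 and SMAD7, an inhibitor of TGF-beta signalling. Among integrins 4 of 16 rose, 7 adjusted over the list alone: ITGA10, ITGA1, ITGA5 and ITGB5 (camera adjusted p = 4.59e-06, and adjusted p = 0.248 with an estimated correlation). Of 25 TGF-beta response genes 6 rose, 11 adjusted over the list alone, among them ANGPTL4, ID3, TGIF1 and LTBP1, while ID2 fell (camera adjusted p = 4.78e-06, and adjusted p = 0.248 with an estimated correlation). FN1, FBN1 and COL1A1 were the 3 of 27 extracellular matrix genes that rose, 9 adjusted over the list alone, and ADAMTS1, SERPINE2 and CTSD the 3 of 26 matrix proteases and inhibitors, also 3 adjusted over the list alone. Their camera adjusted p were 0.000689 and 0.00399, with adjusted p = 0.418 for both with an estimated correlation. The matrix list's call ended with the length and GC offsets (adjusted p = 0.101).

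Fatty acid synthesis genes were called higher through ACSS2, SCD and ACSL1, 3 of 19 with the same 3 adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.301 with an estimated correlation). That call ended with the length and GC offsets (adjusted p = 0.0917), without static replicate 1 (0.0537) and without low flow replicate 1 (0.0553). Of 21 glycolysis genes SLC2A1, a glucose transporter, was the 1 that rose, 1 adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.712 with an estimated correlation). Without static replicate 2 that list's adjusted p was 0.156, and without low flow replicate 2 its direction turned, with an adjusted p of 0.844.

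Many genes of the cell division cycle were lower under low flow. In the list of G2 and mitosis genes 27 of 35 fell, 34 adjusted over the list alone, and 0 rose, with a median log2 fold change of -0.46 (camera adjusted p = 2.12e-30, and adjusted p = 0.248 with an estimated correlation). UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell 1.65-fold from 115.8 to 70.1 CPM (adjusted p = 0.00204), PTTG1 (securin) 1.56-fold, CKS2 1.52-fold and the spindle checkpoint kinase BUB1B 1.54-fold. Of 34 S phase and DNA replication genes 13 fell, 29 adjusted over the list alone, among them TYMS, UHRF1, MCM10 and RFC2 by 1.35-fold to 1.52-fold (camera adjusted p = 9.45e-16, and adjusted p = 0.418 with an estimated correlation). Replication-dependent histone genes had 6 of 24 lower, 12 adjusted over the list alone (camera adjusted p = 4.59e-06, and adjusted p = 0.248 with an estimated correlation). H1-2 fell 1.36-fold at 43.8 CPM in static, and H3C3, H3C12 and H2AC17 fell from under 2 CPM. The histone values need not reflect the cell cycle, since they did not fall alone. Genes annotated as structural RNAs, 134 in all, belong to a class that like most histone transcripts lacks poly(A) tails. Their median log2 fold change was -0.41, with 9 lower and 0 higher. Many of them bear pseudogene names, so their reads need not come from RNAs without poly(A) tails. RN7SK, a nuclear RNA without a poly(A) tail (chromosome 6, 52995621 to 52995948), had the largest decrease among named genes with a mean of at least 4 CPM, from 33.0 to 4.73 CPM (log2 fold change -2.81, SE 0.28, adjusted p = 0.00469).

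Ribosomal protein genes had 17 of 84 lower, 22 adjusted over the list alone, including RPL22, RPL35 and RPL26L1 at 1.41-fold to 1.44-fold (camera adjusted p = 5.77e-10, and adjusted p = 0.441 with an estimated correlation). RPL3L, lower at under 1 CPM, can share reads with RPL3. Among heat shock genes the mitochondrial chaperones HSPD1, HSPE1 and HSPA9 and the co-chaperone CHORDC1 fell, 4 of 21 with 5 adjusted over the list alone (camera adjusted p = 3.25e-05, and adjusted p = 0.441 with an estimated correlation). DDIT4, an mTORC1 inhibitor induced by stress and hypoxia, fell from 548 to 292 CPM (adjusted p = 0.000116). With SHMT2 it made up the 2 of 25 amino acid response genes that fell, with 17 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.76e-06, and adjusted p = 0.418 with an estimated correlation). The hypoxia-induced genes HILPDA and ANKRD37 fell 2.26-fold and 2.25-fold, and ID2, HES7, C11orf96 and S1PR5 fell 2.16-fold to 3.08-fold. The hypoxia list as a whole was not called (camera adjusted p = 0.0835), and its median log2 fold change was 0.35. Of its 28 genes 2 rose and 3 fell, with 5 higher and 3 lower adjusted over the list alone. The pseudogenes RPS2P46 and RPSAP47, lower by 2.37-fold and 2.30-fold, can share reads with their parent genes. Of 29 immediate early genes EGR1, EGR2, BTG2, MYC and DUSP5 fell and DUSP4 rose, with 10 lower and 3 higher adjusted over the list alone. That list's camera adjusted p was 0.0239, with an adjusted p of 0.712 with an estimated correlation, 0.115 without static replicate 2 and 0.468 without low flow replicate 2.

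In all, 672 genes were higher and 722 lower under low flow, 77 and 93 of them at least 2-fold. The YAP target CCN2 (log2 fold change 0.07, adjusted p = 0.798) and CCN1 (0.26, adjusted p = 0.618) did not pass, nor did PTHLH (0.53, adjusted p = 0.0868), FOS, ANKRD1, KLF2, IL11, MMP1, CXCR4, VEGFA, CXCL8, IL6, HMOX1 or PIEZO1. The counts depended on single libraries: they were 310 higher and 317 lower without static replicate 1, 39 and 46 without static replicate 2, 1509 and 1493 without low flow replicate 1, 151 and 106 without low flow replicate 2, 275 and 333 without high flow replicate 1, and 245 and 296 without high flow replicate 2. Of the 65 named genes that passed, 60 still passed with the length and GC offsets, and fewer without static replicate 2. None changed direction with the offsets.

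**Figure D1:**
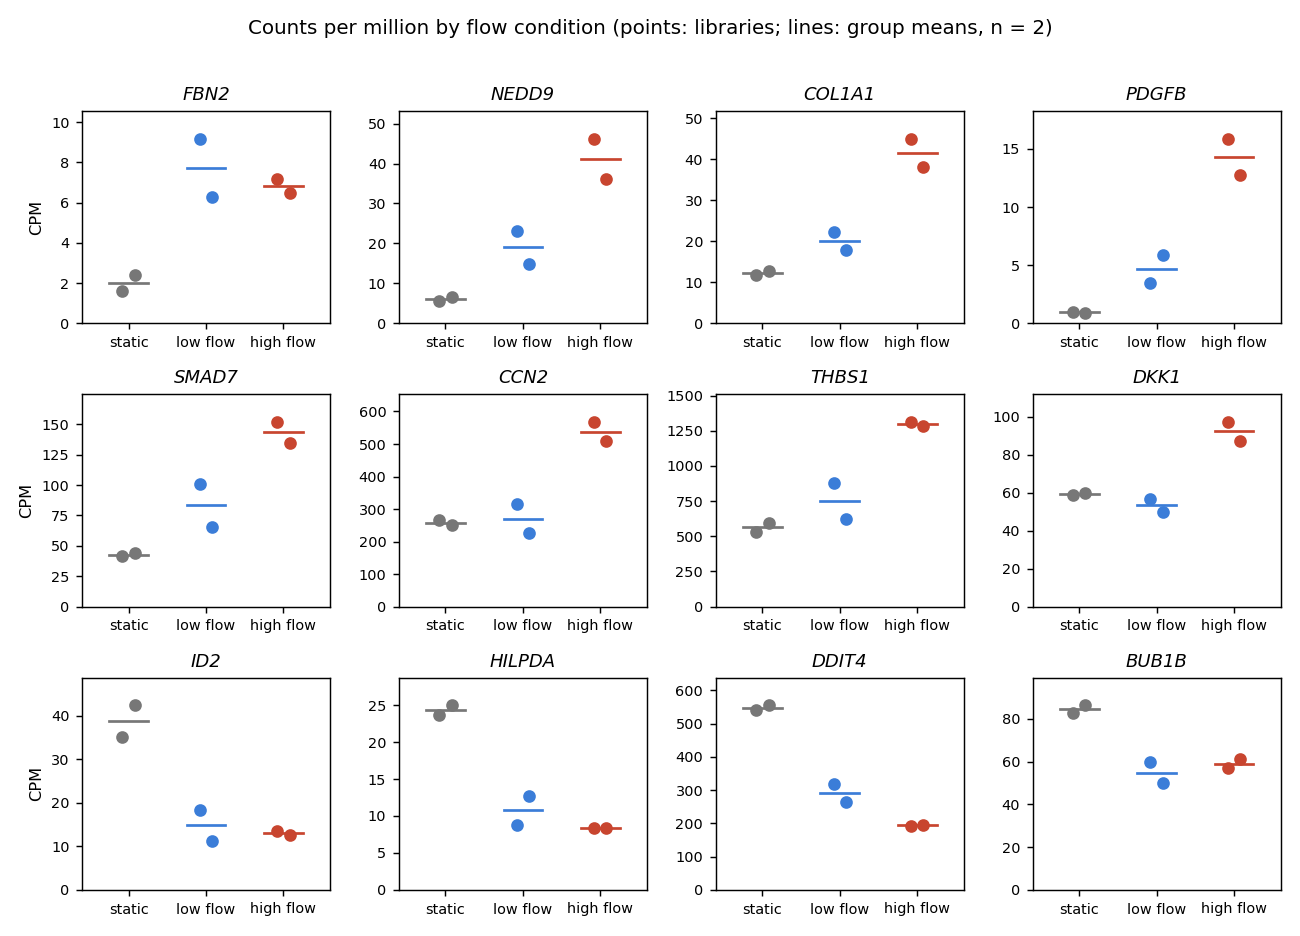
CPM (vertical axes, starting at 0) of 12 genes in the static, low flow and high flow libraries; points are libraries and lines are means of 2 libraries. Mean COL1A1 was 12.2 CPM in static, 20.1 in low flow and 41.5 in high flow, while mean CCN2 was 257.5, 270.7 and 538.3 CPM.

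Many of the same genes were higher under high flow than static, and further genes passed. Passing under only 1 flow rate is no test of a difference between the rates. Lane and flow rate cannot be told apart in this comparison. PDGFB, which encodes a platelet-derived growth factor chain, rose 15.4-fold, from 0.93 to 14.3 CPM (log2 fold change 3.95, SE 0.29, adjusted p = 4.47e-06). It had risen under low flow as well, to 4.63 CPM (log2 fold change 2.32, adjusted p = 0.00138), where its mean expression was below the limit for naming. NEDD9 rose 6.70-fold, LOXL4 4.16-fold, EDN1 3.70-fold and SMAD7 3.34-fold. COL1A1, the alpha-1 chain of type I collagen, rose from 12.2 to 41.5 CPM (3.39-fold, adjusted p = 1.47e-06). FBN2, the nuclear receptor NR4A3, the pseudogene FER1L4 and the co-chaperone DNAJB1 rose 2.98-fold to 3.36-fold. DNAJB1 no longer passed with only the 4 libraries compared, nor without either static or either low flow library.

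Of 27 extracellular matrix genes 15 rose, with 17 higher and 1 lower adjusted over the list alone and a median log2 fold change of 0.40 (camera adjusted p = 5.77e-12, and adjusted p = 0.176 with an estimated correlation). Besides COL1A1 they included THBS1 (thrombospondin 1), from 562 to 1299 CPM, and COL7A1 and HSPG2, at 1.61-fold and 1.57-fold. Of 25 TGF-beta response genes 16 rose, 18 adjusted over the list alone, including ANGPTL4, BHLHE40, ID3 and KLF10 at 1.74-fold to 2.34-fold, while ID2 fell 2.97-fold (camera adjusted p = 3.71e-14, and adjusted p = 0.124 with an estimated correlation). Of 26 matrix proteases and inhibitors 7 rose, 10 adjusted over the list alone, among them ADAMTS1 (2.52-fold), the urokinase gene PLAU (1.93-fold), CTSD and SERPINE2 (camera adjusted p = 1.89e-05, and adjusted p = 0.288 with an estimated correlation). The integrin genes ITGA10, ITGA5, ITGA1 and ITGB5 rose, 4 of 16, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000113, and adjusted p = 0.288 with an estimated correlation).

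Among osteolytic and bone metastasis genes 5 of 24 rose, 5 adjusted over the list alone: ADAMTS1, PTHLH, DKK1, JAG1 and IL11, while RUNX2 fell (camera adjusted p = 0.00142, and adjusted p = 0.187 with an estimated correlation). PTHLH, the gene of parathyroid hormone-related protein, rose from 5.76 to 12.5 CPM (2.16-fold, adjusted p = 0.00101), and DKK1, a secreted Wnt inhibitor, rose 1.56-fold. IL11 rose 1.47-fold with an adjusted p of 0.0496, and did not pass with the length and GC offsets. The YAP and TEAD targets CCN2 (2.09-fold), CCN1, F3, AJUBA, AMOTL2 and ARHGEF17 rose, 6 of 25, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0170, and adjusted p = 0.513 with an estimated correlation). Of 26 actin cytoskeleton and SRF targets 7 rose, 7 adjusted over the list alone, including TLN1, TAGLN, TGFB1I1 and PDLIM7 (camera adjusted p = 0.0130, and adjusted p = 0.513 with an estimated correlation). With the length and GC offsets both calls ended, at adjusted p = 0.119 for the YAP and TEAD list and 0.254 for the actin list. They also ended without static replicate 1 (YAP and TEAD, 0.146) and without high flow replicate 1 (actin, 0.137). Shear stress and mechanosensing genes had 10 of 25 higher and P2RX7 lower, with 12 higher and 4 lower adjusted over the list alone (camera adjusted p = 3.51e-06, and adjusted p = 0.124 with an estimated correlation). PTGS2, KLF4 and PKD1 rose 1.51-fold to 1.69-fold, PIEZO1, a mechanically gated channel, rose 1.31-fold, and KLF2 did not pass (adjusted p = 0.591). With the length and GC offsets the log2 fold change of PIEZO1, high flow against static, was -0.00374 (adjusted p = 0.983).

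Glycolysis genes had 6 of 21 higher, 11 adjusted over the list alone, with SLC2A1, PFKL, SLC16A3 and GPI at 1.32-fold to 1.83-fold, and LDHB lower (camera adjusted p = 5.51e-05, and adjusted p = 0.513 with an estimated correlation). The hypoxia list went both ways: 6 of 28 rose, 9 adjusted over the list alone, including ANGPTL4, SLC2A1, PFKFB3 and PLOD1, while HILPDA fell 2.92-fold, DDIT4 2.82-fold and ANKRD37 by 0.84 on the log2 scale. Its camera adjusted p was 0.0199, with an adjusted p of 0.637 with an estimated correlation and 0.255 without static replicate 1.

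Lower under high flow were some stress-response targets of ATF4, the regulator of amino acid supply. Of 25 such genes 12 fell, 16 adjusted over the list alone, including DDIT4, ASNS, TRIB3 and PSAT1, and VLDLR rose (camera adjusted p = 4.54e-08, and adjusted p = 0.332 with an estimated correlation). The endoplasmic reticulum stress genes ERN1, DDIT3, MANF and XBP1 fell 1.27-fold to 1.54-fold, 4 of 22 with 5 adjusted over the list alone (camera adjusted p = 0.00904, and adjusted p = 0.332 with an estimated correlation). Cell cycle lists were lower as under low flow: 16 of 35 G2 and mitosis genes fell, 22 adjusted over the list alone, among them HMMR, NUF2, PTTG1 and CKS2 (camera adjusted p = 6.59e-12, and adjusted p = 0.332 with an estimated correlation). Of 34 S phase genes 12 fell, 19 adjusted over the list alone, including POLE2, PRIM1, POLD3 and MCM10 (camera adjusted p = 6.70e-09, and adjusted p = 0.513 with an estimated correlation). Histone genes had 12 of 24 lower, 14 adjusted over the list alone, with a median log2 fold change of -0.94 (camera adjusted p = 6.66e-09, and adjusted p = 0.124 with an estimated correlation). The 134 structural RNAs fell less, with a median of -0.14, 9 lower and 3 higher. They leave open whether the histone values reflect the cell cycle in this comparison. Ribosomal protein genes had 16 of 84 lower, 18 adjusted over the list alone (camera adjusted p = 4.66e-06, and adjusted p = 0.513 with an estimated correlation). Without static replicate 1 the ribosomal and endoplasmic reticulum stress calls ended (adjusted p = 0.0538 and 0.0558). RN7SK fell from 33.0 to 3.26 CPM (adjusted p = 0.00102), ID2 2.97-fold, HES7 2.72-fold, LRRC49 2.49-fold, C11orf96 3.41-fold and EGR1 2.15-fold. The pseudogenes TMSB4XP4, RPS2P46 and RPL6P27, lower by 2.66-fold to 3.51-fold, can share reads with their parent genes.

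In all, 1549 genes were higher and 1329 lower under high flow than static, 217 and 290 of them at least 2-fold. Of the fixed panel FOS, ANKRD1, MMP1, CXCR4, VEGFA, CXCL8, IL6 and HMOX1 did not pass. Log2 fold changes rose with the GC content of the transcript across 13854 genes (Spearman rho = 0.433), and with the length and GC offsets 915 genes were higher and 1162 lower. The counts were 215 higher and 152 lower without static replicate 2, 147 and 101 without high flow replicate 1, and 563 and 298 without high flow replicate 2. Of the 82 named genes that passed, 38 still passed without static replicate 2 and 39 without high flow replicate 1. The length and GC offsets ended 12 of the 82 calls and turned PIEZO1.

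**Figure D2:**
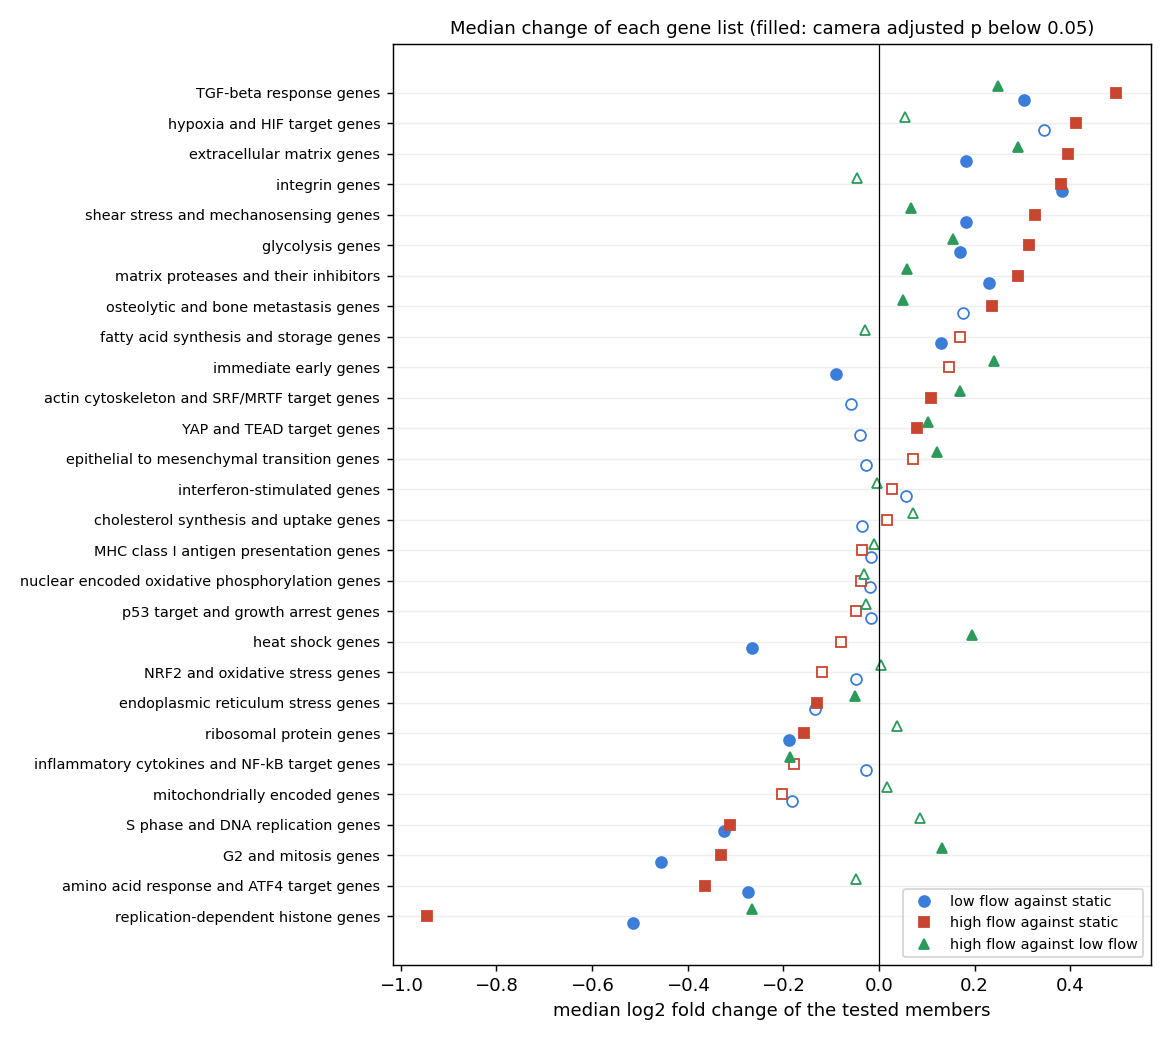
Median log2 fold change of the tested members of each of the 28 gene lists (horizontal axis) in the 3 comparisons; filled symbols passed camera's adjusted p threshold of 0.05 with the preset correlation. TGF-beta response genes had medians of 0.30 under low flow and 0.50 under high flow against static, and G2 and mitosis genes of -0.46 and -0.33.

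Between the flow rates, 50 genes were higher and 19 lower under high flow. NR4A3 rose 3.25-fold (log2 fold change 1.70, SE 0.20, adjusted p = 0.00219), PDGFB 3.08-fold, KRTAP2-3 2.57-fold, EGR3 2.21-fold and EDN1 2.18-fold. COL1A1 rose 2.06-fold (adjusted p = 0.00111), SNAI2, a transcription factor of the mesenchymal programme, 1.84-fold, and DKK1 1.73-fold. MIR29B2CHG fell 2.65-fold, the arrestin-family gene ARRDC3 1.98-fold, the phosphodiesterase PDE4B 1.78-fold and CDKN1B, which encodes the cell cycle inhibitor p27, 1.62-fold. SPRY1, ZNF267 and DDIT4 fell by 0.59 to 0.67 on the log2 scale. TMSB4XP4, H2BC19P and H2BC20P, pseudogenes that can share reads with other genes, were lower by 1.80-fold to 2.10-fold.

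YAP and TEAD targets had 4 of 25 higher, 4 adjusted over the list alone: CCN2 (1.99-fold, adjusted p = 0.00444), AMOTL2, F3 and AJUBA (camera adjusted p = 9.30e-09, and adjusted p = 0.259 with an estimated correlation). Immediate early genes had NR4A3, EGR3 and MYC higher and DUSP6 lower of 29, with 7 and 1 adjusted over the list alone (camera adjusted p = 9.15e-09, and adjusted p = 0.422 with an estimated correlation). The extracellular matrix genes COL1A1 and THBS1 rose, 2 of 27 with 6 adjusted over the list alone, as did BHLHE40, CCN2 and ANGPTL4 among 25 TGF-beta response genes, with 9 higher and 1 lower adjusted over the list alone. Camera adjusted p were 2.05e-10 and 1.97e-09, with adjusted p = 0.252 for both with an estimated correlation. ADAMTS1 rose 1.69-fold with DKK1 among 24 osteolytic genes, 4 adjusted over the list alone, and with PLAU (1.62-fold) among 26 matrix proteases, 3 adjusted over the list alone. The osteolytic list had a camera adjusted p of 0.00296 and an adjusted p of 0.252 with an estimated correlation, and the protease list 0.00644 and 0.427. SNAI2 was the 1 of 20 epithelial to mesenchymal transition genes and EDN1 the 1 of 25 shear stress genes that rose, with 1 higher in the former and 4 higher and 1 lower in the latter adjusted over the list alone. Those lists had camera adjusted p of 0.0454 and 0.0244, with adjusted p = 0.325 and 0.312 with an estimated correlation, the shear stress list 0.0807 with the length and GC offsets, and the transition list 0.0769 without the expression filter.

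Lists were also called in which 0 members passed alone over all genes. Heat shock, actin, G2 and mitosis, and glycolysis lists ranked higher under high flow, with camera adjusted p of 1.97e-09, 1.07e-06, 3.78e-06 and 0.00324 and adjusted p = 0.325, 0.325, 0.505 and 0.660 with an estimated correlation. Adjusted over the list alone, 5 of 21 heat shock, 3 of 26 actin, 1 of 35 G2 and mitosis and 0 of 21 glycolysis genes passed. Without low flow replicate 1 the glycolysis list turned to lower (adjusted p = 0.537). Inflammatory cytokine, histone and endoplasmic reticulum stress lists ranked lower, with camera adjusted p of 0.00042, 0.00296 and 0.0423 and adjusted p = 0.448, 0.252 and 0.448 with an estimated correlation. Adjusted over the list alone, 4 of 26, 0 of 24 and 0 of 22 passed. Without 1 of the 4 flow libraries at a time, the calls of the endoplasmic reticulum stress, G2 and mitosis, histone, protease, shear stress and epithelial to mesenchymal transition lists each ended at least 1 time.

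This comparison was the least secure. Both high flow libraries came from another lane, and log2 fold changes rose with transcript GC content (Spearman rho = 0.634 across 13854 genes). The trend was uneven between libraries. Deviations from each gene's mean correlated with GC content at 0.648 in high flow replicate 1 and 0.31 in high flow replicate 2. In low flow replicates 1 and 2 these values were -0.365 and -0.0813. Most calls also depended on high flow replicate 1, as given below. With the length and GC offsets 26 genes were higher and 13 lower. Without high flow replicate 1 the counts were 3 and 0, and without high flow replicate 2 they were 19 and 1. Of the 28 named genes that passed, 0 still passed without high flow replicate 1 and 9 without high flow replicate 2, and 21 with the length and GC offsets. They were 127 and 54 without low flow replicate 1, 142 and 91 without low flow replicate 2, and 30 and 13 without either static library. CCN1 (log2 fold change 1.01, adjusted p = 0.365), PTHLH (0.59, adjusted p = 0.211) and SMAD7 (0.78, adjusted p = 0.255) did not pass, nor did FOS, EGR1, ANKRD1, PTGS2, KLF2, IL11, MMP1, CXCR4, VEGFA, CXCL8, IL6, HMOX1 or PIEZO1.

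Against static, the flow rates shared many calls. Of the genes higher under low flow 503 were also higher under high flow, or 74.9%, and of those lower 523 were also lower, or 72.4%, with 0 called in opposite directions. Independent lists of these sizes would share 50.3 and 46.4 genes. All 6 libraries were also simulated with no gene changed and with the simulated static group shared by both comparisons. Means of 0.76 and 0.48 calls were shared there. With no gene changed few calls of any kind arise, so these means are no baseline for the overlap. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.80 and a Spearman rho of 0.77, with simulated means of 0.63 and 0.53. Their covariance was 0.229 with a simulated mean of 0.0805. The simulation drew each gene independently, so deviations that many genes of a static library share are left out. The simulated correlations and covariance may therefore be too low. The 2 static libraries could not be split with 2 for each comparison, so part of the excess in shared calls may come from the shared controls.

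Most markers of other cell types were under 1 CPM. The labels describe the cells as endothelial cancer cells, whereas MDA-MB-231 is a breast carcinoma line. Of 10 endothelial markers PECAM1, TIE1, ESAM and KDR reached a mean of 1 CPM over the conditions, and CDH5, VWF and CLDN5 were under 0.2 CPM in each. TIE1 was at 35.1, 40.0 and 42.2 CPM and ESAM at 30.7, 33.3 and 37.1 CPM in static, low flow and high flow, and neither passed in any comparison. PECAM1 rose from 8.44 to 13.7 CPM under low flow and 12.4 CPM under high flow. From static to high flow KDR fell from 1.43 to 0.56 CPM (log2 fold change -1.39, adjusted p = 0.0214). ERG, near the floor, fell from 0.38 to 0.056 CPM (-2.80, adjusted p = 0.0379). Of 6 erythroid markers 0 reached 1 CPM. PTPRC, the common leukocyte marker, was at most 0.14 CPM, and CD68 was 304.9, 270.4 and 298.4 CPM in static, low flow and high flow. Of 11 osteoblast and stromal markers COL1A1, LEPR, PHEX and BGLAP reached 1 CPM, while IBSP and OMD had 0 counts. In the luminal epithelial set 8 of 12 reached 1 CPM, led by KRT18 at 227 CPM under high flow, and in the basal set 2 of 7 did.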

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

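The length and GC offsets were chosen after seeing the data, and all other alternatives before. RLE normalization ended no call of a named gene or list, and leaving out mitochondrial and top genes ended no call of a named gene. RLE normalization and leaving out those genes also kept every count within 1.5 times. Without the expression filter 1327 genes were higher under low flow than static, and 168 higher and 73 lower under high flow than low flow. DESeq2 called 89 genes higher in the latter comparison. With only the 4 libraries compared, 264 genes were higher and 337 lower under low flow, and 29 and 12 between the flow rates, while 2080 were higher and 1802 lower under high flow than static. With the length and GC offsets 915 genes were higher under high flow than static and 26 than low flow, and PIEZO1, high flow against static, turned to -0.00374 on the log2 scale. Of the genes called higher under high flow than static, 733 were also called with the offsets.

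With an estimated correlation 0 lists were called in any comparison. The directional test fry called 3 lists under low flow, those of shear stress, fatty acid synthesis and histone genes. Under high flow it called 7, these 3 and the osteolytic, extracellular matrix, matrix protease and TGF-beta lists. Between the flow rates it called 0. Of the 45 camera calls 9 held with fry. The G2 and mitosis list did not pass (fry adjusted p = 0.0665 under low flow and 0.0736 under high flow). The correlation of fold changes was 0.69 without the filter and 0.70 in thinned counts. The cause of these shifts was not tested.

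With the replicate block 411 genes were higher under low flow and 496 lower. It ended the calls of 9 of 65 named genes under low flow, 1 of 82 under high flow and 2 of 28 between the flow rates, and of no list. Deviations of libraries with the same number correlated at -0.144 between static and low flow, -0.0514 between static and high flow and 0.138 between the flow rates, and the labels do not say what a number marks, so the samples share only a number.

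Leaving out 1 library leaves its condition with 1 library, assumed to vary like the others. Genes higher and lower then ranged from 39 to 1509 and 46 to 1493 under low flow, from 147 to 2105 and 101 to 1810 under high flow, and from 3 to 142 and 0 to 91 between the flow rates. Lists called ranged from 13 to 18, 13 to 19 and 12 to 18. The correlation ranged from 0.68 to 0.88, but the value expected with no change was simulated only for all 6 libraries, so these values do not measure how well the flow rates match. No named gene that passed with all 6 libraries changed direction in that comparison. This decides little about robustness. The rule took the largest and smallest fold changes only where the groups did not overlap, so leaving out 1 library could hardly turn them. List members were picked by p in the direction of the call. The camera direction turned for the list glycolysis genes, low flow against static, without low flow replicate 2 (adjusted p = 0.844, and 2.56e-06 without replicate 1). It also turned for the list glycolysis genes, high flow against low flow, without low flow replicate 1 (0.537, and 5.99e-11 without replicate 2). The static libraries were the shallowest, and in counts thinned to the smallest total 664 genes were higher and 719 lower under low flow.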

Other observations

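Of the 672 genes higher and 722 lower under low flow, 503 and 523 were also called in that direction under high flow. A few of the others were also called between the flow rates, in the opposite direction. MIR29B2CHG rose by a log2 fold change of 1.38 under low flow and was at -0.03 under high flow against static. KLF9, a transcription factor induced by glucocorticoids, rose by 0.60 under low flow (adjusted p = 0.00345) and was at 0.12 under high flow, and SPRY1, an inhibitor of receptor tyrosine kinase signalling, rose by 0.43 and was at -0.21. MYC and PPP1R10 fell by 0.40 and 0.46 under low flow and were at 0.32 and 0.14 under high flow. With the clone AC083843.3 and the pseudogene HMGN2P5, these were the 7 genes called in one direction by low flow and in the other between the flow rates. They were chosen after their values were seen, and the lane of the high flow libraries applies to them as well.

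Single genes were called in lists that were not. The oxidative stress list had camera adjusted p of 0.143 under low flow and 0.108 under high flow, the p53 list 0.336 and 0.218, and the epithelial to mesenchymal transition list 0.940 and 0.253, with members called both ways. Under low flow and high flow respectively, the aldo-keto reductases AKR1C1 (0.81 and 0.78 on the log2 scale) and AKR1C3 (0.83 and 0.70) were higher. The oxidative stress genes GCLM (-0.40 and -0.45) and PGD (-0.35 and -0.31) were lower. CDKN1C and BBC3 were lower under both flow rates, and CDKN1A, which encodes the cell cycle inhibitor p21, was higher under high flow (0.63). The epithelial splicing factor ESRP1 was lower (-1.28 and -1.48) while SNAI2 was higher (0.46 and 1.33). These genes were picked after their values were seen.

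In the next 3 paragraphs, the tests of structural RNAs and of the lane were chosen after the result was seen, and the length and GC adjustment itself was added after the data were seen.

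The first pattern weighed is the fall of G2 and mitosis genes under low flow, in libraries that share a lane. Adjusting each library for its trend with transcript length and GC content left the list's median log2 fold change at -0.47. Thinning every library to the smallest total left the list's median at -0.45. Thinning keeps each gene's expected share of a library's counts, so it could hardly move this median and decides nothing about depth. Leaving out any 1 library of the comparison left the median at -0.39 or lower. The offsets and the left-out libraries argue against a length and GC trend or 1 library alone as the whole cause. A difference that goes with the lower depth of the static libraries stays open. A change in the share of cycling cells under flow also stays open as an untested hypothesis. Any unrecorded difference in how the conditions were grown or harvested may act the same way, and stays open too.

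The second is the fall of RNAs without poly(A) tails, such as RN7SK and histone transcripts, under both flow rates. If more such RNA had been carried into the static libraries, 134 structural RNAs that share no exon with another gene should be lower under both flow rates, and with fewer cells in S phase alone they should stay level. Their median log2 fold change was -0.41 under low flow (9 called lower, 0 higher, 0% of 10000 expression-matched random lists as low), past the bound for carry-over. Under high flow the median was -0.14 (9 lower, 3 higher, 3.53% of random lists as low), between the bounds. The libraries differed: median deviations were -0.0653 and 0.0716 in the high flow and 0.0994 and 0.0926 in the static libraries. The bounds, set after the pattern was seen, had to be met in both comparisons, so neither explanation was decided. RN7SK is itself 1 of the 134. Most structural RNAs were near the floor (median 0.401 CPM), and many bear pseudogene names. The random lists were matched for expression but not for transcript length, with which log2 fold changes rose under low flow (Spearman rho = 0.174). Structural RNAs above 2 CPM went different ways. SNORD14E (-2.64 under low and -2.88 under high flow) and SNORA33 (-1.21 and -0.855) were called lower with RN7SK. SNORD83A was called higher under high flow (0.96). RN7SL2 (-0.43 and 0.41), SNORD104 (-0.21 and -0.09), AC012531.3, SNORA73B and SNORD3A were not called. For high flow against low flow, structural RNAs had a median of 0.22 and histone genes of -0.27, in opposite directions. Carry-over, fewer S phase cells and flow itself all stay open as candidate explanations.

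The third is the 69 genes that differ between high flow and low flow. After the length and GC adjustment 37 were still called in the same direction, 32 calls ended and 0 changed sign. The bound of 35 was set before the adjustment but with the 69 calls known, and was passed narrowly. Median transcript GC content was 0.541 for genes called higher, 0.430 for those called lower and 0.485 for all tested genes. The median size of the 69 was 0.72 on the log2 scale before and 0.69 after (quartiles 0.51 and 0.97). The fitted trend thus took little off the fold changes. The genes were selected by their differences in the same data. What remains therefore does not decide how far such a trend made the calls. The other lane and file of the high flow libraries cannot be told apart from the flow rate, because 0 lanes hold both. Flow rate remains an open explanation, untested apart from lane.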
